A study of Mus musculus with 15 samples.

How the data were processed

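Uteri of ovariectomized CD-1 mice given vehicle, E2 or E3 were profiled on 15 one-colour Agilent mouse arrays, 3 for each of 5 groups, from 500 ng of total RNA labelled with Cy3. The authors deposited intensity values: per the file headers, the processed signal of Feature Extraction 9.5.3.1 (9.5 in the processing notes of the labels) is an intensity on a linear scale. Per the same headers it was background-subtracted with a spatial detrend, detrended multiplicatively within the array, and had low values replaced by a surrogate; it was not normalized between arrays. The series value table was checked against these signals and was equal to them, with a largest relative difference of 0, so it gives no independent alternative. The headers name mm7 as the build of the probe positions. A RefSeq table of a later build was used for gene names only.

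Each array held 45018 spots, of which 43379 were not controls and represented 41174 probes. Spots flagged in the files as non-uniform or as population outliers were left out, repeated probes were averaged, and 53 probes left without a value on some array were dropped. Probes were named by their RefSeq accession (22951), by another RefSeq accession listed for the probe (124), by a current symbol (6582) or by a unique synonym (3077), and 8440 kept the name in the file, which gave 27669 names. Of the 20313 genes tested, 15153 had a symbol and 5160 did not. Each array's log2 signal was reduced by its own 75th percentile over non-control probes. A gene was represented by its probe with the highest mean over all arrays, and it was tested if that probe was well above background on all 3 arrays of at least 1 group, a call taken from the files. Arrays give no counts, so depth is given as the 75th percentile of the signal and the share of probes well above background.

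A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (files were read with the package data.table, version 1.17.8), with moderated variances and Benjamini-Hochberg adjustment over the genes tested in each comparison. A gene was called at an adjusted p under 0.05, and counts at 2-fold or more are given beside. The comparisons were each oestrogen and time with vehicle, E2 with E3 at each time, 24 h with 2 h for each oestrogen, and the difference of the E2 minus E3 differences between the times. Intervals are at 95%. The labels give no pairing of replicate numbers across groups, so replicate number was not a term of the model.

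The response score of an array was its mean change from vehicle over the genes called at 2-fold or more with the mean of both oestrogens at that time, with the sign of that change; E2 and E3 were compared by an exact two-sided permutation test of 3 arrays against 3. Overlaps between comparisons that share the vehicle arrays are given beside values from 20 draws simulated with no effect and the same shared controls. Lists of genes for processes and for cell types, 27 in all with at least 5 members tested, were written from general knowledge of the uterus. They were tested with camera at a preset correlation of 0.01, adjusted over the 243 tests of lists and comparisons, and again with an estimated correlation and with fry.

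The genes named in the text follow a rule. For each comparison these were the 10 largest rises and 10 largest falls among genes called, with all 3 arrays of one group above all 3 of the other, a probe well above background on all 3 arrays of the brighter group, and a symbol. For 24 h with 2 h and for the difference of differences these were 5 and 5, the latter without the condition on the order of arrays. Up to 4 members of each list described were added, as were Esr1, Pgr, Greb1, Igf1, Ltf, C3, Fos, Cdkn1a, Ccnb1, Mki67, Lcn2 and Muc1 in every comparison. Some genes that the rule gives are not reported here. The groups, the model, the lists, this rule and the main alternatives were chosen before the data were examined; alternatives with scan day, and some for lists and overlaps, were added afterwards.

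The alternatives were quantile normalization, the array median as the scale, normexp background on the mean spot and median local background intensity with an offset of 50, no filter on dim probes, a probe well above background on all 15 arrays, the mean of a gene's probes, every probe on its own, a stricter adjusted p of 0.01, a 2-fold minimum, a fit to the groups of the comparison alone, trended and robust variances, array weights, replicate number as a block, slide as a random block (estimated correlation 0.144) and as a fixed block over the treated arrays, scan day as a fixed block, scan day 1 alone, and leaving out each array in turn. Normal values were simulated gene by gene from level and spread, with changes added to 50 genes of each size in E2 24 h. The pipeline recovered 18% at 1.5-fold, 60% at 2-fold, 84% at 4-fold and 92% at 8-fold, with 5 false calls. It called a list shifted by 0.5 on the log2 scale and 0 others, which does not test correlated genes. Control probes were used only to look at the arrays and are in no comparison.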

Results

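Gene expression was measured in the uterus of ovariectomized CD-1 mice, an outbred strain, after an injection of saline vehicle (100 µl) or of 250 ng of an oestrogen. The labels abbreviate the oestrogens as E2 and E3, read here by their usual meaning as estradiol and estriol; estriol carries an additional hydroxyl group on the D ring. Uteri were taken 2 h or 24 h after the oestrogen, and the collection time of the vehicle uteri is not given in the sources used here. The 15 one-colour arrays made 5 groups of 3: vehicle, E2 2 h, E3 2 h, E2 24 h and E3 24 h. The 75th percentile of the signal ran from 1053 (E3 24 h replicate 3) to 1854 (E3 2 h replicate 2), and the share of probes well above background from 63.1% (E3 24 h replicate 2) to 80.0% (vehicle replicate 1). The 3 arrays per group limit the precision of every value. The labels do not say whether they are separate animals, so the p-values measure the spread between these samples, which may be technical. That spread is pooled over the 5 groups, so E3 24 h standard errors and p-values tend to be too small. Across genes, which are not independent replicates, the correlation between arrays of a group was 0.986 to 0.992 in vehicle, both 2 h groups and E2 24 h, but 0.962 to 0.974 in E3 24 h. The median standard deviation per gene was 0.275 on the log2 scale in E3 24 h and 0.166 to 0.20 in the other groups. On the third principal component, with 8.44% of the variance, E3 24 h replicate 3 lay at -89.0 and the other arrays from -12.4 to 30.5. The arrays lay on 6 slides scanned on 3 days. All vehicle arrays shared 1 slide with no other group on it, and E2 and E3 arrays of one time never shared a slide, so slide and group are largely confounded. A slide effect was therefore fitted as a random block, as a fixed block where the comparison leaves out vehicle, and through the scan day.

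In what follows, a change is a log2 ratio of group means with its standard error and n = 3 arrays per group, and its p is limma's, adjusted over the 20313 genes tested. Among the genes named by rank, except for the difference of differences, all 3 arrays of one group lay above all 3 of the other, which chance gives for 10% of genes. Of 243 tests of gene lists, 92 were called by camera with a preset correlation, and 0 of these held with an estimated correlation, where the smallest adjusted p was 0.0544.

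The comparisons of 2 h with vehicle ask which transcripts had changed soon after each oestrogen. All 21 measured immediate early and early transcription factor genes rose with E2 (median 2.82) and with E3 (median 2.90). Fos, a subunit of the AP-1 transcription factor (probe on chromosome 12, 83478431 to 83478490, build mm7), rose by 5.38 ± 0.41 with E2 (adjusted p = 1.8e-06) and by 5.23 ± 0.41 with E3 (adjusted p = 2.2e-06). Fosl1, another AP-1 subunit, rose by 4.98 ± 0.35 and 5.43 ± 0.35, and Arc, an activity-regulated immediate early gene, by 6.17 ± 0.31 and 6.16 ± 0.31. All 21 also passed with each oestrogen when adjusted over the list alone. The list test gave adjusted p = 9.8e-20 for E2 and 1.3e-20 for E3, against adjusted p = 0.054 for each with an estimated correlation.

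Of 21 measured early oestrogen-response genes of the uterus, 16 rose, 3 fell and 2 were not called, with E2 (median 2.67) and with E3 (median 2.57), the same counts as adjusted over the list alone. Inhbb, an inhibin and activin subunit, rose by 5.38 ± 0.81 with E2 (adjusted p = 2.4e-04) and 5.43 ± 0.81 with E3 (adjusted p = 2.2e-04), and Gadd45g, a growth arrest and DNA damage-inducible gene, by 4.61 ± 0.49 and 4.71 ± 0.49. Cdkn1a, the cyclin-dependent kinase inhibitor p21 (chromosome 17, 27293819 to 27293878), rose by 3.89 ± 0.34 and 3.29 ± 0.34. Greb1, an oestrogen-induced coactivator gene, rose by 3.82 ± 0.47 and 3.72 ± 0.47. Pgr, the progesterone receptor, rose by 1.99 ± 0.33 and 1.82 ± 0.33, and Igf1, a growth factor, by 1.13 ± 0.19 and 1.47 ± 0.19; another probe of Pgr gave 3.93 with E2 and 4.11 with E3, and another probe of Igf1 gave 2.87 and 3.21. Esr1, the oestrogen receptor alpha, had a value of -0.13 ± 0.11 with E2 (adjusted p = 0.37) and fell by 0.33 ± 0.11 with E3 (adjusted p = 0.028). That call was lost without any 1 vehicle array (-0.35, -0.31 and -0.34), E3 2 h replicate 1 (-0.21) or 2 (-0.35), in both scan day settings (-0.26 and -0.21), with median scaling (-0.09) and with the mean of probes (-0.18), and another probe gave -0.04. The list test gave adjusted p = 2.9e-09 for each oestrogen, against adjusted p = 0.33 for each with an estimated correlation.

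Of 38 ribosome biogenesis and nucleolar genes, 27 rose with E2 (median 0.83; 29 when adjusted over the list alone) and 30 with E3 (median 0.84; 31 over the list alone), and 0 fell. Rrs1, a ribosome biogenesis regulator, rose by 2.38 ± 0.27 with E2 (adjusted p = 3.2e-05) and 2.16 ± 0.27 with E3, and Nolc1, a nucleolar phosphoprotein, by 1.84 ± 0.21 and 1.88 ± 0.21. The list test gave adjusted p = 4.8e-13 for E2 and 4.9e-14 for E3 (adjusted p = 0.52 for each with an estimated correlation). Of 27 genes of endoplasmic reticulum folding and the unfolded protein response, 16 rose and 1 fell with each oestrogen (the same over the list alone), with medians of 0.41 and 0.42. Atf4, a stress-response transcription factor, rose by 2.18 ± 0.17 and 2.32 ± 0.17, and Hspa5, the main chaperone of the endoplasmic reticulum, by 1.23 ± 0.20 and 1.45 ± 0.20. That test gave adjusted p = 2.2e-05 for E2 and 7.2e-06 for E3 (adjusted p = 0.52 for each with an estimated correlation).

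Sterol biosynthesis genes rose as a list: with E2, 10 of 23 rose and 4 fell (median 0.44), and with E3, 12 rose and 3 fell (median 0.53). Camera gave the sterol list adjusted p = 0.012 with E2, or adjusted p = 0.75 with an estimated correlation, and 11 and 4 passed when adjusted over the list alone. The sterol list had adjusted p = 0.0041 with E3, or adjusted p = 0.71 with an estimated correlation, and the same counts passed when adjusted over the list alone. Of 16 glucose uptake and glycolysis genes, 7 rose and 0 fell with E3 (median 0.42), whereas the list was not called with E2 (6 rose, 1 fell, median 0.29); Hk2, a hexokinase, rose by 1.93 ± 0.34 and 2.15 ± 0.34. Camera gave the glycolysis list adjusted p = 0.0049 with E3, or adjusted p = 0.59 with an estimated correlation, and 8 and 1 passed when adjusted over the list alone. The glycolysis list had adjusted p = 0.064 with E2, and the same counts passed when adjusted over the list alone. It was called with E2 without vehicle replicate 3 (median 0.25, adjusted p = 0.03), within scan day 1 (0.23, 0.046), with median scaling (0.47, 0.043), normexp (0.29, 0.044) and no filter on dim probes (0.29, 0.023). Interferon-response genes were lower: 11 of 23 fell with E2 (median -0.68) and 13 with E3 (median -0.80), and 0 rose. Camera gave the interferon list adjusted p = 0.023 with E2, or adjusted p = 0.84 with an estimated correlation, and 11 passed when adjusted over the list alone. The interferon list had adjusted p = 0.011 with E3, or adjusted p = 0.82 with an estimated correlation, and 13 passed when adjusted over the list alone. Rsad2, an antiviral enzyme induced by interferon, fell by 2.63 ± 0.29 on the log2 scale with E2 and by 3.14 ± 0.29 with E3. Without vehicle replicate 3 the interferon list was not called with E2 (median -0.56, adjusted p = 0.073). Genes of the G1/S transition and DNA replication had medians of 0.10 with E2 (9 higher, 1 lower of 40) and 0.01 with E3 (7 higher, 3 lower). Camera gave the replication list adjusted p = 0.043 with E2, or adjusted p = 0.78 with an estimated correlation, and 8 and 0 passed when adjusted over the list alone. The replication list had adjusted p = 0.19 with E3, and 6 and 2 passed when adjusted over the list alone. The E2 call was lost without vehicle replicate 1 (median 0.02), vehicle replicate 2 (0.10) or E2 2 h replicate 1 (0.09), with slide as a random block (0.10, adjusted p = 0.071) and within scan day 1 (0.09, adjusted p = 0.069).

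Among the largest rises at 2 h, Trim15, a tripartite motif protein (chromosome 17, 35012696 to 35012755), was at least 208-fold higher with E2 and at least 257-fold with E3, with vehicle not well above background. Such bounds set the bright group's mean against, on each array of the dim group, the higher of the lowest signal among probes well above background and the probe's own signal. Gdf15, a secreted stress-induced cytokine (chromosome 8, 69084712 to 69084771), rose by 7.20 ± 0.31 and 6.77 ± 0.31. Klk1b24, a kallikrein, rose by 7.60 ± 0.68 and 6.93 ± 0.68, and Krt86, a keratin, by 7.39 ± 1.01 and 7.51 ± 1.01; both belong to families of close paralogs, whose transcripts a probe may share. Among the falls, Hgf, hepatocyte growth factor (chromosome 5, 15580130 to 15580189), fell by 3.89 ± 0.31 with E2 and 3.81 ± 0.31 with E3, although another probe of the gene gave -0.76 and -0.66. Bmf, a pro-apoptotic Bcl-2 family gene, fell by 3.70 ± 0.25 and 3.89 ± 0.25, with -1.08 and -1.30 at another probe. Of 25 Wnt and homeobox patterning genes, 4 rose and 8 fell with E2 (median -0.25), and 4 rose and 10 fell with E3 (median -0.45). Camera did not call the list, with adjusted p = 0.26 and 0.19, and when adjusted over the list alone 4 rose and 9 fell with E2 and 4 rose and 11 fell with E3. Its member Wnt4, a Wnt ligand, rose by 3.27 ± 0.40 and 3.09 ± 0.40, and Fzd1, a Wnt receptor, fell by 2.64 ± 0.12 and 2.66 ± 0.12.

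In total 7852 genes changed with E2 at 2 h, 3157 higher and 4695 lower, of which 3293 by 2-fold or more. With E3, 8169 changed, 3369 higher and 4800 lower, of which 3429 by 2-fold or more. The split depends on the scaling: with each array's median as its scale, 4207 were higher and 3115 lower with E2, and 4871 and 2927 with E3. That scaling moved the median change of all genes from -0.14 to 0.04 with E2 and from -0.16 to 0.08 with E3. With slide as a random block 6601 genes changed with E2 and 6941 with E3, with scan day as a fixed block 7530 and 8053, and within scan day 1 8364 and 8298, of which 7183 and 7312 were among the genes called on all arrays. With these settings in the same order, the immediate early list had medians of 2.80, 2.85 and 2.82 with E2 and 2.88, 2.92 and 2.93 with E3, the ribosome biogenesis list 0.81, 0.78 and 0.93, and 0.82, 0.88 and 0.89, and the interferon list -0.68, -1.002 and -0.77, and -0.85, -0.82 and -0.99.

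**Figure D1:**
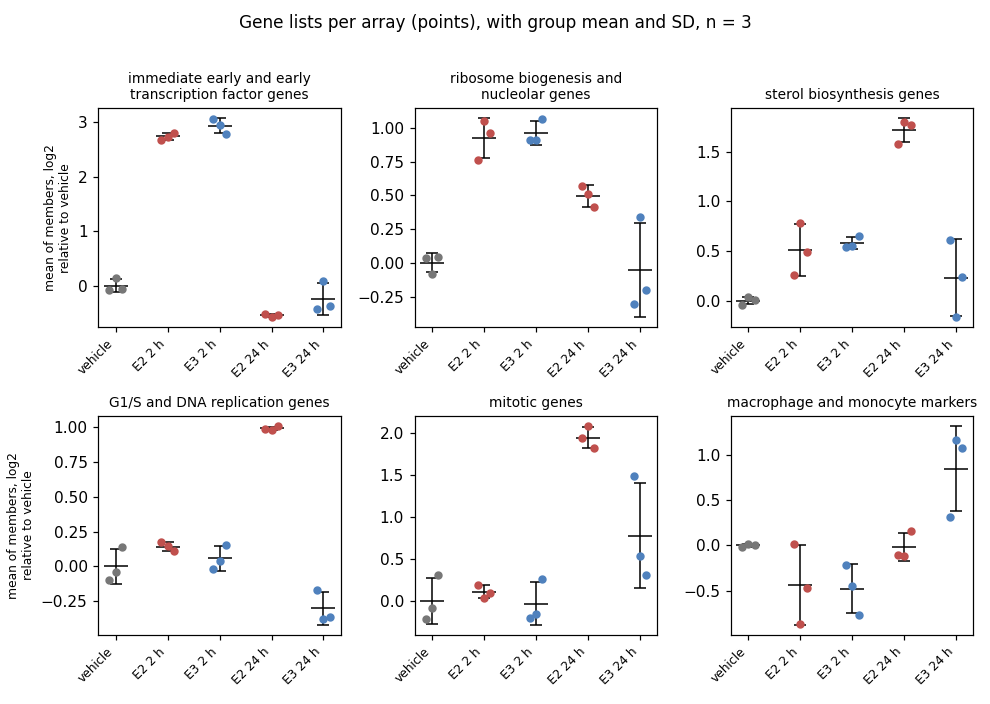
Mean level of the measured members of 6 gene lists in each array (y axis, log2 relative to the vehicle mean), by group (x axis); points are the 3 arrays of a group in replicate order, with the group mean and standard deviation. Immediate early and ribosome biogenesis genes are highest at 2 h with both oestrogens, whereas replication, mitotic and sterol genes are higher in E2 24 h than in E3 24 h by medians of 1.22, 1.22 and 1.37.

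The comparison of E2 with E3 at 2 h asks whether the 2 oestrogens, given at the same dose, differed early. Fos differed by 0.15 ± 0.41 (95% interval -0.75 to 1.05), Greb1 by 0.10 ± 0.47 (-0.93 to 1.13), Pgr by 0.17 ± 0.33 (-0.55 to 0.89), Igf1 by -0.34 ± 0.19 (-0.75 to 0.07) and Cdkn1a by 0.61 ± 0.34 (-0.13 to 1.34), each as E2 minus E3. Immediate early genes were lower with E2 as a list (median -0.18), as were glucose uptake and glycolysis genes (median -0.21), with 0 members called in either list, over all genes or over the list alone. The immediate early list had adjusted p = 0.0032, or adjusted p = 0.59 with an estimated correlation. Camera gave the glycolysis list adjusted p = 0.0013, or adjusted p = 0.59 with an estimated correlation. The immediate early call was lost without E2 2 h replicate 1 (median -0.12, adjusted p = 0.052), without E3 2 h replicate 1 (-0.12, 0.11), within scan day 1 (-0.09, 0.19) and with slide as a fixed block (-0.02, 0.78). The glycolysis call held within scan day 1 (-0.17, 0.0018) and not with slide as a fixed block (-0.20, 0.22). Eosinophil and mast cell markers were higher with E2 as a list (median 0.68, 0 members called), but not without E3 2 h replicate 3 (0.33, 0.22) or with slide as a fixed block (0.45, 0.52). The eosinophil and mast cell list had adjusted p = 0.0021, or adjusted p = 0.52 with an estimated correlation, and 0 members passed when adjusted over the list alone. Extracellular matrix genes (median 0.14), smooth muscle markers (-0.16) and replication genes (0.08) were also called by camera, with adjusted p = 0.011, 0.041 and 0.0498, and adjusted p = 0.70, 0.81 and 0.78 with an estimated correlation. Of their members 0 were called, and 0, 0 and 1 passed when adjusted over the list alone. With fry 0 of the 3 were called (adjusted p = 0.40, 0.61 and 0.51). The matrix call was lost without E2 2 h replicate 1 (0.08) or E3 2 h replicate 1 (0.06), with scan day as a block (0.05), within scan day 1 (-0.03) and with slide as a fixed block (-0.053), the last 2 with a negative median. The smooth muscle call was lost without E2 2 h replicate 2 (-0.09) or 3 (-0.13) or E3 2 h replicate 2 (-0.20) or 3 (-0.09). It was also lost with slide as a random (-0.17) or fixed (-0.39) block, scan day (-0.15) or replicate number (-0.16) as a block, quantile normalization (-0.11) and normexp (-0.15). The replication call was lost without any 1 of the E2 2 h arrays (0.09, 0.05 and 0.10) or without E3 2 h replicate 1 (0.03) or 2 (0.08). It was also lost with scan day (0.05), replicate number (0.08) or slide (0.06) as a fixed block, within scan day 1 (0.02), with median scaling (0.02) and with no filter on dim probes (0.08).

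No single gene differed between E2 and E3 at 2 h: limma called 0, with 750 genes at an unadjusted p under 0.05 where 1015.65 are expected by chance and a smallest adjusted p of 0.405. The 95% interval of the difference lay within 2-fold for 80.4% of genes, with a median width to either side of 0.42, so larger differences in the remaining genes are not excluded, and a missed threshold does not show that the oestrogens act alike. With only these groups in the fit 1 gene was called, Best1 (3.84, adjusted p = 0.0016), and without E2 2 h replicate 2 another, Tescl (-4.73, adjusted p = 4.4e-04), both chosen after their values were seen. Blocks for slide called 0 genes, with 707 unadjusted as a random and 1120 as a fixed block, as did scan day as a block (689 unadjusted) and scan day 1 alone (720). Quantile normalization, median scaling, normexp background and array weights also called 0, with 621, 817, 548 and 2191 unadjusted.

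The overlap of both 2 h responses was 2850 genes higher and 3947 lower with each oestrogen and 0 in opposite directions, where the products of the counts over all genes give 523.6 and 1109.4. Across genes the 2 sets of changes had a correlation of 0.949 and a covariance of 0.799. The same 3 vehicle arrays serve both comparisons, and in 20 simulated draws with no effect that alone gave a correlation of 0.502, a covariance of 0.0527 and 0 shared calls. The vehicle arrays cannot be split so that each part keeps 2, so part of the excess may come from the shared controls.

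**Figure D2:**
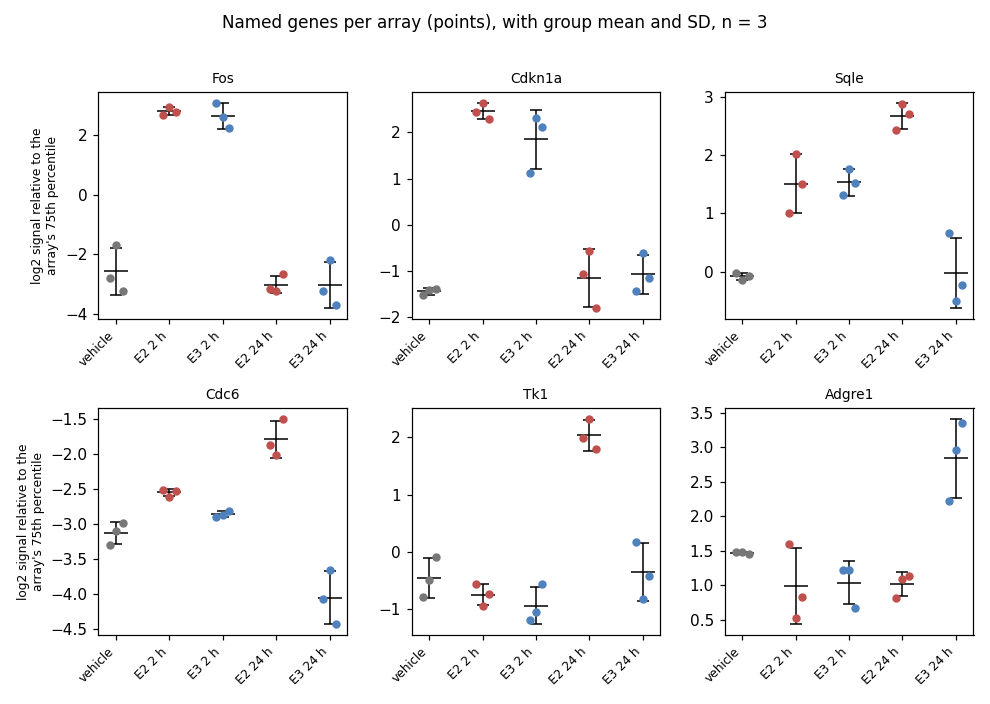
Level of 6 genes in each array (y axis, log2 relative to the array's 75th percentile), by group (x axis); points are the 3 arrays of a group, with the group mean and standard deviation. Fos and Cdkn1a are high in both 2 h groups, Sqle, Cdc6 and Tk1 are higher in E2 24 h than in E3 24 h, by 2.69, 2.26 and 2.39, and Adgre1 is lower in E2 24 h than in E3 24 h by a difference of -1.83.

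The comparisons of 24 h with vehicle ask which transcripts differed a day after each oestrogen. With E2, 37 of 40 genes of the G1/S transition and DNA replication rose and 1 fell (median 0.97), and all 35 mitotic genes rose (median 1.99). Camera gave the replication list adjusted p = 3.1e-15 with E2, or adjusted p = 0.17 with an estimated correlation, and 38 and 1 passed when adjusted over the list alone. The mitotic list had adjusted p = 4.7e-17 with E2, or adjusted p = 0.52 with an estimated correlation, and 35 passed when adjusted over the list alone. Tk1, thymidine kinase (chromosome 11, 117924836 to 117924895), rose by 2.48 ± 0.26 (adjusted p = 3.7e-05), and Gins2, a part of the replicative helicase, by 1.60 ± 0.15 (adjusted p = 1.6e-05). Ccnb1, a mitotic cyclin, rose by 2.47 ± 0.33 (adjusted p = 1.6e-04), and Mki67, a marker of cycling cells, by 1.76 ± 0.26 (adjusted p = 2.7e-04). With E3, by contrast, 10 of the 40 replication genes fell and 0 rose (median -0.29), whereas 15 of the 35 mitotic genes rose and 0 fell (median 0.78). Camera gave the replication list adjusted p = 1.8e-04 with E3, or adjusted p = 0.59 with an estimated correlation, and 10 passed when adjusted over the list alone. The mitotic list had adjusted p = 8.8e-09 with E3, or adjusted p = 0.64 with an estimated correlation, and 22 passed when adjusted over the list alone. Without E3 24 h replicate 1 its median was 0.45, and it was still called. Cdc6, a replication licensing factor (chromosome 11, 99030298 to 99030357), fell by 0.92 ± 0.18 with E3 (adjusted p = 0.0076) and Mcm2, a helicase subunit, by 0.86 ± 0.20 (adjusted p = 0.014), while Ccnb2, a mitotic cyclin, rose by 1.54 ± 0.29 (adjusted p = 0.0072). Ccnb1 rose by 1.37 ± 0.33 with E3 (adjusted p = 0.017; 0.82 at another probe), but its call was lost without vehicle replicate 1 (1.21), vehicle replicate 2 (1.253) and in both scan day settings (1.32 with the block, 1.42 within scan day 1).

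Sterol biosynthesis genes rose with E2 in 22 of 23 cases and fell in 0 (median 1.65). Camera gave the sterol list adjusted p = 1.8e-12 with E2, or adjusted p = 0.39 with an estimated correlation, and 22 passed when adjusted over the list alone. Fdps, a farnesyl diphosphate synthase, rose by 2.76 ± 0.24 (1.19 at another probe) and Sqle, squalene epoxidase, by 2.75 ± 0.29. With E3, 4 rose and 0 fell (median 0.19), so the list was not called, but it was without E3 24 h replicate 2 (median 0.37, adjusted p = 1.8e-04), without vehicle replicate 2 (0.28, 0.049), with scan day as a block (0.34, 4.8e-04) and within scan day 1 (0.37, 2.2e-04). The sterol list had adjusted p = 0.073 with E3, and 4 passed when adjusted over the list alone. Glucose uptake and glycolysis genes rose with E2 (12 of 16, 1 fell, median 0.94) and with E3 (9 of 16, 0 fell, median 0.44); Eno1, an enolase, rose by 1.52 ± 0.16 with E2 and Pgk1, a glycolytic kinase, by 0.70 ± 0.15 with E3. Camera gave the glycolysis list adjusted p = 9.5e-05 with E2, or adjusted p = 0.52 with an estimated correlation, and the same counts passed when adjusted over the list alone. The glycolysis list had adjusted p = 6.9e-04 with E3, or adjusted p = 0.57 with an estimated correlation, and 9 passed when adjusted over the list alone. The E3 call was lost with quantile normalization (median 0.09).

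Late secretory epithelial genes rose with both oestrogens: 16 of 25 with E2 (median 2.08) and 10 with E3 (median 1.53), and 0 fell. Camera gave the late secretory list adjusted p = 2.4e-04 with E2, or adjusted p = 0.63 with an estimated correlation, and 16 passed when adjusted over the list alone. The late secretory list had adjusted p = 1.4e-05 with E3, or adjusted p = 0.59 with an estimated correlation, and 11 passed when adjusted over the list alone. Within scan day 1 the E3 median was 0.61, still called. Of the E3 arrays this leaves out only replicate 2, with a mean level of 2.81 against 0.97 and 0.83. Epithelial markers as a class also had positive medians, 0.55 with E2 (4 of 18 rose, 0 fell) and 0.48 with E3 (1 rose, 0 fell), so a larger epithelial share is not set apart from a rise within the epithelium. Camera gave the epithelial list adjusted p = 0.069 with E2 and adjusted p = 0.045 with E3, or adjusted p = 0.81 with an estimated correlation, and 4 and 0 passed when adjusted over the list alone. The E3 call was lost without E3 24 h replicate 2 (0.15), vehicle replicate 2 (0.42) or 3 (0.44), and in both scan day settings (0.36 and 0.15). It was also lost with slide as a random block (0.50), quantile normalization (0.27), median scaling (0.62), normexp (0.45) and fry (adjusted p = 0.20). With E2 the list was called without vehicle replicate 1 (0.64) or E2 24 h replicate 2 (0.72), within scan day 1 (0.57) and with no filter on dim probes (0.55). Clca1, a secreted regulator of mucus, rose by 3.51 ± 0.66 with E2 (adjusted p = 0.0012) and 2.74 ± 0.66 with E3 (adjusted p = 0.016), and Muc1, an epithelial mucin, by 2.75 ± 0.45 (adjusted p = 5.5e-04) and 2.04 ± 0.45 (adjusted p = 0.012). With E3, Clca1 and Muc1 were no longer called without vehicle replicate 2 (2.41 and 1.63) or within scan day 1 (1.87 and 1.65). Ltf, lactotransferrin, had values of 1.098 ± 0.93 with E2 (adjusted p = 0.36) and 1.53 ± 0.93 with E3 (adjusted p = 0.26). Complement C3 had 0.64 ± 0.46 (adjusted p = 0.28) and 1.07 ± 0.46 (adjusted p = 0.12). Lcn2, lipocalin, had 1.99 ± 0.88 with E3 (adjusted p = 0.13). With E2 it rose by 2.94 ± 0.88 (adjusted p = 0.018), but not without vehicle replicate 1 (2.86), vehicle replicate 2 (2.82) or E2 24 h replicate 3 (2.43). Extracellular matrix genes rose with E2 (16 of 30, 4 fell, median 0.78) and with E3 (12 rose, 1 fell, median 0.48). Camera gave the matrix list adjusted p = 1.2e-04 with E2, or adjusted p = 0.57 with an estimated correlation, and 18 and 4 passed when adjusted over the list alone. The matrix list had adjusted p = 1.3e-05 with E3, or adjusted p = 0.52 with an estimated correlation, and 12 and 2 passed when adjusted over the list alone. Col1a1, a chain of type I collagen, rose by 2.45 ± 0.29 with E2 and 1.95 ± 0.29 with E3.

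Other lists were lower at 24 h. Immediate early genes fell with E2 (9 of 21, 0 rose, median -0.43), among them Egr1, a zinc-finger factor, by 1.49 ± 0.20. Camera gave the immediate early list adjusted p = 0.0057 with E2, or adjusted p = 0.59 with an estimated correlation, and 9 passed when adjusted over the list alone. With E3, 4 fell and 0 rose (median -0.17), and the list was called without E3 24 h replicate 2 (-0.33, 9.8e-05) or vehicle replicate 1 (-0.22, 0.034), with scan day as a block (-0.18, 0.014) and within scan day 1 (-0.33, 8.6e-05). It was also called with quantile normalization (-0.27, 0.024), normexp (-0.13, 0.02) and no filter on dim probes (-0.14, 0.036). The immediate early list had adjusted p = 0.073 with E3, and 4 passed when adjusted over the list alone. Fos had -0.44 ± 0.41 with E2 (adjusted p = 0.42) and -0.47 ± 0.41 with E3 (adjusted p = 0.44). Wnt and homeobox patterning genes fell with E2 (11 of 25, 0 rose, median -0.53) and with E3 (7 of 25, 0 rose, median -0.39). Camera gave the Wnt and homeobox list adjusted p = 0.0052 with E2, or adjusted p = 0.17 with an estimated correlation, and 11 passed when adjusted over the list alone. The Wnt and homeobox list had adjusted p = 0.0073 with E3, or adjusted p = 0.17 with an estimated correlation, and 7 passed when adjusted over the list alone. Ptch1, a hedgehog receptor, fell by 2.50 ± 0.29 and 1.47 ± 0.29, and Axin2, a Wnt target, by 1.31 ± 0.19 with E2. Esr1 fell by 0.64 ± 0.11 with E2 (adjusted p = 6.5e-04) and 0.57 ± 0.11 with E3 (adjusted p = 0.0071), but another probe gave 0.05 and -0.06. Igf1 rose by 1.14 ± 0.19 with E2 (adjusted p = 5.7e-04; -0.12 at another probe) and had 0.49 ± 0.19 with E3 (adjusted p = 0.081).

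Among the largest changes with E2 at 24 h, Inmt, a methyltransferase (chromosome 6, 55134146 to 55134205), fell by 5.94 ± 0.69 (adjusted p = 6.6e-05), Coch, cochlin (chromosome 12, 49618352 to 49618411), by 5.22 ± 0.33 (adjusted p = 3.3e-06), and Igfbp3, a carrier of insulin-like growth factors, by 3.36 ± 0.18 (adjusted p = 2e-06). Crtac1, a cartilage acidic protein, rose by 5.27 ± 0.77 (adjusted p = 2.6e-04), and Rhd, a blood group gene, was at least 13.9-fold higher, with vehicle not well above background. With E3 the rises named by rank included kallikreins, Klk1 by 6.63 ± 1.29 (adjusted p = 0.0077; 3.70 at another probe) and Klk1b5 by 6.61 ± 1.252 (adjusted p = 0.007), again close paralogs, Tescl by 4.65 ± 0.92 (adjusted p = 0.008), and Atp2c2, a calcium pump of the secretory pathway, by 4.49 ± 0.93 (adjusted p = 0.0094). Klk1, Klk1b5 and Atp2c2 rose with E2 too, by 4.37 ± 1.29 (adjusted p = 0.016; 1.75 at another probe), 4.50 ± 1.252 (adjusted p = 0.012) and 4.90 ± 0.93 (adjusted p = 0.0013). Nap1l5, a nucleosome assembly protein-like gene (chromosome 6, 58873509 to 58873568), fell by 2.12 ± 0.21 with E3 (adjusted p = 0.001), Rimklb by 2.43 ± 0.36 (adjusted p = 0.0033) and Has2, a hyaluronan synthase, by 2.31 ± 0.48 (adjusted p = 0.0094).

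In total 8814 genes changed with E2 at 24 h (4279 higher, 4535 lower, 3326 by 2-fold or more) and 4136 with E3 (1971 higher, 2165 lower, 1063 by 2-fold or more). With the median as the scale the splits were 6191 and 3025 with E2 and 3012 and 1315 with E3, and with normexp background 1880 and 1258 with E3. Median scaling moved the median change of all genes from -0.02 to 0.20 with E2 and from 0.00 to 0.14 with E3. The E3 count fell to 1423 without vehicle replicate 1, to 1466 without vehicle replicate 2 and to 2293 without E3 24 h replicate 2, and to 1 with only these groups in the fit (Tescl, 4.65, adjusted p = 0.0127). With slide as a random block 7748 genes changed with E2 and 2473 with E3, with scan day as a block 8277 and 2360, and within scan day 1 8497 and 2300, of which 7657 and 1950 were among the genes called on all arrays. With these 3 settings in the same order, the replication list had medians of 0.97, 0.99 and 0.98 with E2 and -0.29, -0.30 and -0.23 with E3, and the mitotic list 1.99, 2.06 and 2.00 with E2 and 0.76, 0.85 and 0.89 with E3.

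The overlap at 24 h was 1539 genes higher and 1841 lower with each oestrogen and 33 in opposite directions (9 without vehicle replicate 1 or 2, 15 without vehicle replicate 3 or E3 24 h replicate 3, and 99 without E3 24 h replicate 1), against 415.2 and 483.3 from the products of the counts. The correlation across genes was 0.734, with 0.491 simulated from the shared vehicle arrays alone, and the covariance 0.382, with 0.0515 simulated. The number shared fell from 3380 to 1886 within scan day 1, to 1248 and 1286 without vehicle replicate 1 or 2, and to 1961 without E3 24 h replicate 2. Of the 33 opposite genes, 25 were higher with E2 and lower with E3, and 9 of these were replication genes, which made 9 of the 10 of that list called with both oestrogens. Cdc45, a helicase loading factor, rose by 1.254 with E2 and fell by 0.54 with E3, Mcm5 rose by 1.46 and fell by 0.44, and Uhrf1, a factor that maintains DNA methylation, rose by 1.41 and fell by 0.82. Ccne2, a G1/S cyclin, rose by 1.24 with E2 and had -1.05 with E3, where normexp background turned it to 0.08.

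The comparison of E2 with E3 at 24 h asks whether the oestrogens differed a day after the same dose. All 40 genes of the G1/S transition and DNA replication were higher with E2 (median 1.22), and so were 28 of 35 mitotic genes, with 0 lower (median 1.22). Camera gave the replication list adjusted p = 1.3e-37, or adjusted p = 0.054 with an estimated correlation, and 40 passed when adjusted over the list alone. The mitotic list had adjusted p = 4.1e-17, or adjusted p = 0.52 with an estimated correlation, and 34 passed when adjusted over the list alone. Tk1 differed by 2.39 ± 0.26 (adjusted p = 2.1e-04), Cdc6 by 2.26 ± 0.18 (adjusted p = 5.1e-05), Uhrf1 by 2.23 ± 0.19 (adjusted p = 6.7e-05) and Top2a, a topoisomerase of dividing cells, by 1.68 ± 0.26 (adjusted p = 0.0015). Sterol biosynthesis genes were higher with E2 in 21 of 23 cases and lower in 0 (median 1.37), among them Sqle by 2.69 ± 0.29 (adjusted p = 1.8e-04). Camera gave the sterol list adjusted p = 1.7e-19, or adjusted p = 0.17 with an estimated correlation, and 23 passed when adjusted over the list alone. Mki67 differed by 0.95 ± 0.26 (adjusted p = 0.029; 95% interval 0.38 to 1.51) and Ccnb1 by 1.098 ± 0.33 (adjusted p = 0.044; 0.37 to 1.82). Mki67 was not called without E2 24 h replicate 1 (0.87) or 2 (0.85), E3 24 h replicate 2 (0.70) or 3 (0.92), and neither gene in either scan day setting (0.87 and 0.62 for Mki67, 1.102 and 0.97 for Ccnb1). Ccnb1 was not called without any 1 of the E2 24 h arrays (1.02, 1.09, 1.18) or without E3 24 h replicate 2 (1.05) or 3 (0.75).

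Ribosome biogenesis genes were higher with E2 than with E3 at 24 h (17 of 38, 0 lower, median 0.55), as were endoplasmic reticulum folding genes (12 of 27, 1 lower, median 0.42). The ribosome biogenesis list had adjusted p = 4e-11, or adjusted p = 0.57 with an estimated correlation, and 28 passed when adjusted over the list alone. Camera gave the endoplasmic reticulum list adjusted p = 5e-05, or adjusted p = 0.52 with an estimated correlation, and 15 and 2 passed when adjusted over the list alone. Reference genes, often taken as constant, were higher with E2 as well (6 of 15, 0 lower, median 0.27), which is to be set beside these medians. The reference list had adjusted p = 0.0095, or adjusted p = 0.52 with an estimated correlation, and 7 and 1 passed when adjusted over the list alone; it was not called with slide as a fixed block (0.02). Calr, a chaperone, differed by 1.40 ± 0.12 (adjusted p = 5.4e-05). Markers of 3 leukocyte classes were lower with E2: of 16 macrophage and monocyte markers 7 were lower and 0 higher (median -0.97), of 18 lymphocyte and natural killer markers 6 and 0 (median -1.08), and of 12 dendritic and antigen-presentation markers 3 and 0 (median -0.996). Neutrophil markers (median 0.12, adjusted p = 0.64) and eosinophil and mast cell markers (-0.48, adjusted p = 0.27) were not called. E3 24 h replicate 3 had the highest dendritic and lymphocyte levels of its group; without it the macrophage, lymphocyte and dendritic medians were -0.89, -0.95 and -0.76, all called. The macrophage list had adjusted p = 4.1e-05, or adjusted p = 0.59 with an estimated correlation, and 10 passed when adjusted over the list alone. Camera gave the lymphocyte list adjusted p = 3.4e-05, or adjusted p = 0.59 with an estimated correlation, and 8 passed when adjusted over the list alone. The dendritic list had adjusted p = 2.6e-04, or adjusted p = 0.52 with an estimated correlation, and 6 passed when adjusted over the list alone. Adgre1, the macrophage marker F4/80 (listed as Emr1; chromosome 17, 55686649 to 55686708), differed by -1.83 ± 0.30 (adjusted p = 0.002), Csf1r, the macrophage growth factor receptor, by -1.38 ± 0.27 (adjusted p = 0.0061; -0.61 at another probe) and Il2rb, an interleukin receptor subunit, by -1.67 ± 0.32 (adjusted p = 0.0052). Il2rb was not called within scan day 1 (-1.16). Inmt, Coch and Mlana, a melanocyte antigen gene, were lower with E2 by differences of -5.06 ± 0.69, -3.99 ± 0.33 and -3.39 ± 0.34. Interferon-response genes were lower with E2 as a list (0 higher, 2 lower of 23, median -0.56), and immediate early genes too (0 higher, 4 lower of 21, median -0.24). Camera gave the interferon list adjusted p = 6.5e-04, or adjusted p = 0.74 with an estimated correlation, and the same counts passed when adjusted over the list alone. The immediate early list had adjusted p = 0.011, or adjusted p = 0.63 with an estimated correlation, and the same counts passed when adjusted over the list alone. Without E3 24 h replicate 2 these last calls were lost (-0.22, 0.28 and -0.09, 0.43), as they were within scan day 1 (-0.18, 0.6 and -0.13, 0.52), while the late secretory list, not called on all arrays (median 0.31, adjusted p = 0.41), was called without that array (0.97, 2.2e-05).

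In total 3195 genes differed between E2 and E3 at 24 h (1818 higher with E2, 1377 lower, 933 by 2-fold or more), and with the median as the scale 2032 were higher and 972 lower. The count was 1829 without E2 24 h replicate 1, 1831 without E2 24 h replicate 2, 1986 without E3 24 h replicate 3 and 362 with only these groups in the fit. There were 2549 genes with slide as a random block, with scan day as a block 2235, and within scan day 1 3019, of which 1909 were among the genes called on all arrays. With slide as a fixed block limma called 0, with 3221 at an unadjusted p under 0.05; that fit takes its E3 24 h value from replicate 2 alone, the other 2 sharing a slide with no other group. With slide as a random block, scan day as a block, scan day 1 alone and slide as a fixed block, in this order, the replication list had medians of 1.23, 1.20, 1.15 and 1.35, the mitotic list 1.24, 1.24, 1.097 and 1.70, the sterol list 1.42, 1.28, 1.20 and 1.34, and the macrophage list -0.99, -0.82, -0.81 and -0.62, all called. The ribosome biogenesis list had 0.52, 0.60, 0.70 and -0.12, and the endoplasmic reticulum list 0.39, 0.49, 0.52 and 0.11, both not called in the last.

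A response score, the mean change over genes changed by 2-fold or more with the mean of both oestrogens, with the sign of each gene's change, put the size of the responses on one scale. At 2 h, over 3410 genes, it was 1.74 ± 0.17 (SD, n = 3) with E2 and 1.79 ± 0.08 with E3, a difference of -0.05 (exact two-sided permutation p = 0.8). At 24 h, over 2013 genes, it was 1.71 ± 0.03 with E2 and 1.15 ± 0.33 with E3, so that E3 had 67.0% of the E2 score and the difference was 0.56. The exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. The E3 24 h arrays had 0.91, 1.52 and 1.02 as replicates 1, 2 and 3; without replicate 1 the difference was 0.30, without replicate 2 it was 0.730, and with genes changed by 4-fold or more it was 0.830. Within scan day 1 the differences were -0.003 at 2 h (exact permutation p = 1) and 0.789 at 24 h (exact permutation p = 0.333).

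**Figure D3:**
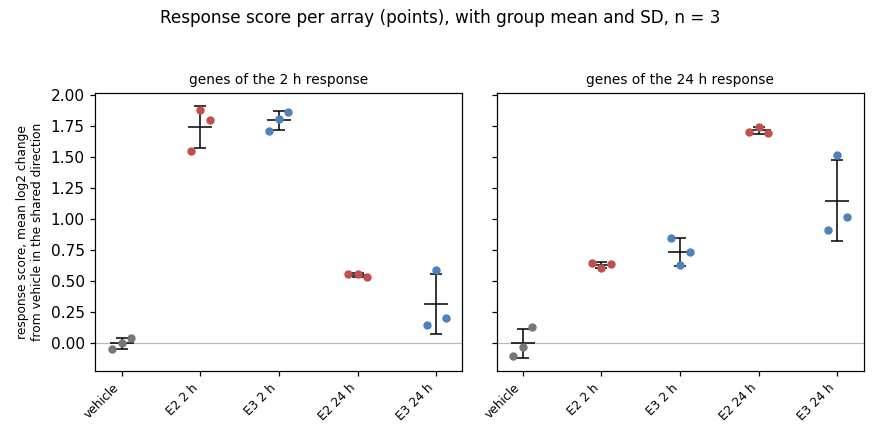
Response score of each array (y axis, mean signed log2 change relative to the vehicle mean over the genes of the 2 h or the 24 h response), by group (x axis); points are the 3 arrays of a group, with the group mean and standard deviation. At 24 h the E2 arrays lie between 1.70 and 1.74 and the E3 arrays between 0.91 and 1.52, whereas at 2 h the groups overlap.

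The comparisons of 24 h with 2 h ask how each response had moved over time. Immediate early genes were lower at 24 h in 20 of 21 cases with E2 (median -3.12) and in all 21 with E3 (median -2.98), and higher in 0. Camera gave the immediate early list adjusted p = 6.7e-17 with E2, or adjusted p = 0.071 with an estimated correlation, and 20 passed when adjusted over the list alone. The immediate early list had adjusted p = 4.8e-19 with E3, or adjusted p = 0.054 with an estimated correlation, and 21 passed when adjusted over the list alone. Fos differed by -5.82 ± 0.41 and -5.70 ± 0.41, Arc by -6.95 ± 0.31 and -6.49 ± 0.31, and Cdkn1a by -3.61 ± 0.34 and -2.91 ± 0.34. Has1, a hyaluronan synthase, differed by -6.16 ± 0.30 with E3 (adjusted p = 6.5e-08), and Egr4, a zinc-finger factor, was at least 136-fold lower at 24 h of E2, where it was not well above background. Pgr was lower at 24 h by differences of -1.29 ± 0.33 and -1.50 ± 0.33 (-3.17 and -4.08 at another probe), and Greb1 by -3.31 ± 0.47 and -3.34 ± 0.47. Replication genes were higher at 24 h with E2 (32 of 40, 1 lower, median 0.86) and lower with E3 (1 higher, 16 lower, median -0.26). Camera gave the replication list adjusted p = 9.5e-07 with E2, or adjusted p = 0.52 with an estimated correlation, and 33 and 2 passed when adjusted over the list alone. The replication list had adjusted p = 2.2e-04 with E3, or adjusted p = 0.59 with an estimated correlation, and 0 and 16 passed when adjusted over the list alone. Mitotic genes were higher at 24 h with E2 (34 of 35, 1 lower, median 1.94) and with E3 (24 of 35, 1 lower, median 0.94). Camera gave the mitotic list adjusted p = 7e-10 with E2, or adjusted p = 0.62 with an estimated correlation, and the same counts passed when adjusted over the list alone. The mitotic list had adjusted p = 0.001 with E3, or adjusted p = 0.83 with an estimated correlation, and 25 and 1 passed when adjusted over the list alone.

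Ribosome biogenesis genes were lower at 24 h than at 2 h with E3 (1 higher, 30 lower of 38, median -0.95) and with E2 (7 higher, 17 lower, median -0.41). Camera gave the ribosome biogenesis list adjusted p = 1.2e-11 with E3, or adjusted p = 0.56 with an estimated correlation, and the same counts passed when adjusted over the list alone. The ribosome biogenesis list had adjusted p = 0.014 with E2, or adjusted p = 0.84 with an estimated correlation, and 7 and 18 passed when adjusted over the list alone. Nolc1 differed by -2.18 ± 0.21 with E3 and -1.65 ± 0.21 with E2. With E3, interferon-response genes were higher at 24 h (20 of 23, 0 lower, median 1.57) and so were macrophage markers (14 of 16, 0 lower, median 1.21), with Rsad2 higher by 3.25 ± 0.29 and Fcgr1, an Fc receptor of macrophages, by 2.09 ± 0.32. Camera gave the interferon list adjusted p = 2e-05 with E3, or adjusted p = 0.64 with an estimated correlation, and 20 passed when adjusted over the list alone. The macrophage list had adjusted p = 5.9e-04 with E3, or adjusted p = 0.63 with an estimated correlation, and 15 passed when adjusted over the list alone. With E2, interferon-response genes were higher at 24 h too (12 of 23, 0 lower, median 0.84), while macrophage markers had a median of 0.23 (5 higher, 1 lower). Camera gave these lists adjusted p = 0.018, or 0.83 with an estimated correlation, and adjusted p = 0.56, and the same counts passed when adjusted over the list alone. The interferon call with E2 was lost without E2 24 h replicate 3 (0.63, 0.087) and with slide as a random (0.87, 0.088) or fixed (0.62, 0.097) block. Rises named by rank with both oestrogens were those of Rnf186, a ubiquitin ligase (6.28 ± 0.64 with E2, 5.20 ± 0.64 with E3), and Trpv6, an epithelial calcium channel (5.03 ± 0.61 and 4.35 ± 0.61). In total 10631 genes differed between the times with E2 (6214 higher at 24 h, 4417 lower) and 10095 with E3 (6073 higher, 4022 lower), where median scaling gave 4859 and 4535 with E3. With slide as a random block the counts were 10688 and 9091, with scan day as a block 9884 and 9055, within scan day 1 9999 and 9520, and with slide as a fixed block 7780 and 134.

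The last comparison asks whether the difference between the oestrogens was itself different at 24 h and at 2 h, by the test of that difference. Replication genes had a larger E2 minus E3 difference at 24 h in 33 of 40 cases and a smaller one in 0 (median 1.21), and sterol biosynthesis genes in 17 of 23 and 0 (median 1.45). Camera gave the replication list adjusted p = 1.3e-32, or adjusted p = 0.054 with an estimated correlation, and 38 passed when adjusted over the list alone. The sterol list had adjusted p = 1.6e-18, or adjusted p = 0.18 with an estimated correlation, and 22 passed when adjusted over the list alone. Cdc6 had a difference of differences of 1.95 ± 0.25 (adjusted p = 0.0028), Uhrf1 of 1.99 ± 0.28 (adjusted p = 0.0033), Sqle of 2.71 ± 0.41 (adjusted p = 0.0045) and Calr of 1.46 ± 0.17 (adjusted p = 0.0015). Among mitotic genes 4 of 35 passed and 31 did not (median 1.06). Camera gave the mitotic list adjusted p = 1.1e-11, or adjusted p = 0.59 with an estimated correlation, and 19 passed when adjusted over the list alone. Macrophage markers moved the other way (0 higher, 2 lower of 16, median -0.89). The macrophage list had adjusted p = 1.9e-04, or adjusted p = 0.59 with an estimated correlation, and 0 and 5 passed when adjusted over the list alone. Mlana had -4.48 ± 0.48 (adjusted p = 0.0014) and Coch -3.63 ± 0.47 (adjusted p = 0.0028). In total 1264 genes passed, 781 with a positive and 483 with a negative difference of differences, 620 of them by 2-fold or more, and with the median as the scale 1084 and 331. The count was 701 with slide as a random block, 189 with scan day as a block, 610 within scan day 1 (382 of them among the genes called on all arrays), 687 with only these groups in the fit, and 432 to 2217 when single arrays were left out. Slide as a fixed block made limma call 0, with 2175 at an unadjusted p under 0.05.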

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

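The tests of a uniformly weaker response and of slide, those of E3 24 h replicate 2, the splits of the 2 h arrays alone, and the settings that use scan day, were chosen only after the results were seen.

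For 1264 genes the E2 minus E3 difference was not the same at 24 h as at 2 h, by a test of the difference between the times. Of 100 drawn splits of the oestrogen labels within each time, 2 gave as many genes, the real one included. The other one gave 1569 and the next highest 1201. These splits also mix the 24 h groups, so they test the difference at 24 h and not a change between the times. With the 24 h groups kept, 3 of the 20 splits of the 2 h arrays gave as many genes, the real one included, the others from 442 to 1625. A set of 20 splits is too small for a share under 0.05. The split with 1569 kept the 24 h arrays in their own groups and mixed only the 2 h arrays, with both 2 h arrays scanned on the later days on the same side. With scan day as a fixed block the real count was 189, and within scan day 1 it was 610. Cdc6, Uhrf1, Sqle and Calr were called in each setting with scan day.

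Replication, mitotic and sterol transcripts were higher with E2 than with E3 at 24 h, by medians of 1.22, 1.22 and 1.37. A scan day effect as the whole cause is argued against by the share of the median difference left within scan day 1, at least 0.874 in the 3 lists. A single deviating array is argued against by the share left when any of the 6 arrays was left out, at least 0.775. A response to E3 that was weaker by one factor for all genes is argued against by the ratio of the E3 to the E2 median, -0.294 for replication, 0.391 for mitotic and 0.114 for sterol genes, against 0.670 over all genes of the 24 h response. Slide stays open, since E2 and E3 arrays of this time never share one. Blocking the treated arrays by slide, the mean of the members differed by 1.405 (95% interval 0.961 to 1.849), 1.671 (-0.678 to 4.020) and 1.585 (0.679 to 2.491). That fit takes E3 24 h from replicate 2 alone, so it decides nothing about slide. Also open is a biological difference between the oestrogens, such as in the time course of replication, which these times cannot test.

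Late secretory and interferon transcripts were higher in E3 24 h replicate 2 than in the other E3 24 h arrays. Mean levels were 2.81 against 0.97 and 0.83, and 2.05 against 0.77 and 0.87. An E2 24 h sample, whole or mixed in, is argued against by the excess of this array over the highest of the E2 24 h arrays and the other E3 24 h arrays, at least 0.641 in both lists. The bound, 2 standard deviations of the E2 24 h arrays (0.249 and 0.440), was set after the levels were seen. The slide and scan day shared with E2 2 h replicate 1 are argued against by the deviation of that array from its group, at most 0.130 of the deviation of this one. The low share of probes above background on this array is argued against as the whole cause by the deviation over the brighter members, at least 0.838 of that over all members. Its share of the E2 24 h response, given above, was the highest of the E3 24 h arrays. Positions between the group means, each array left out of its own, were 0.422, 0.463 and 0.522 in replicate order, about midway for each. The means differ by array, so these neither clear replicate 2 nor set it apart. The second principal component set it nearer to E2 24 h, at -29.0 against 18.7 and 5.30. The first tests, of nearness to E2, were dropped because of the positions. A mixture with another sample and a difference in time or amount of injected E3 or between animals stay open, untested.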

How the results depend on the processing

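The settings with scan day, the changes of normalization and the arrays left out for gene lists and overlaps, and slide as a fixed block for lists, were chosen only after the results were seen. Unless the construction of a setting shows it, the cause of a change was not tested. The layout of the slides, 3 arrays per group and signal over background (63.1% to 80.0% of probes were well above it) limit the values. The signs of called named genes held in each setting run for them except where a turn is listed here. Of 966 values of named genes, quantile normalization kept direction and call in 907 and ended 59 calls, median scaling kept 920 and ended 43, normexp kept 927 and ended 38, the mean of probes kept 926 and ended 37, slide as a random block kept 866 and ended 100, scan day as a block kept 832 and ended 129, and scan day 1 alone kept 829 and ended 128. Slide as a fixed block kept 226 of 494 and ended 257. Vehicle arrays could not be split into parts of 2 for the overlaps, so that alternative was not run.

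Stricter thresholds lower counts by construction. With 2-fold or more, 3293 genes were left for E2 2 h, 3326 for E2 24 h, 3429 for E3 2 h and 1063 for E3 24 h against vehicle, 933 for E2 against E3 at 24 h, 4854 and 4216 for 24 h against 2 h of E2 and E3, 620 for the difference of differences, and 2829 and 774 for the overlaps at 2 h and 24 h. At an adjusted p of 0.01 these were 5220, 5766, 5387 and 865 against vehicle in that order, 1246 for E2 against E3 at 24 h and 208 for the difference of differences. Every probe on its own, which tests more features, gave 13571 for E2 24 h, 6653 for E3 24 h and 16039 for 24 h against 2 h of E2. Without a filter on dim probes E3 24 h had 2690 and the difference of differences 574. The latter had 687 with only the groups compared and 2836 with array weights, where E2 2 h had 12803. With only the groups compared, thus fewer arrays, E2 2 h, E3 2 h and E2 24 h had 8366, 8454 and 8818. E3 24 h, whose wider spread the main fit pools, had 1. E2 against E3 had 1 at 2 h and 362 at 24 h. With genes of 4-fold or more the 24 h score difference was 0.830.

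Slide as a random block gave 2473 for E3 24 h and 701 for the difference of differences, scan day as a block 2360 and 189, and scan day 1 alone 2300 and 610, with 1886 in the 24 h overlap. Slide as a fixed block gave 0 for E2 against E3 at 24 h, 0 for the difference of differences and 134 for 24 h against 2 h of E3. It also turned the medians of the extracellular matrix list for E2 against E3 at 2 h (-0.053) and of the ribosome biogenesis list for E2 against E3 at 24 h (-0.12) and the difference of differences (-0.11). Among genes it turned Rrp12 (-0.25) and Tfrc (-0.34) for E2 against E3 at 24 h, Dkc1 (-0.17) for the difference of differences, and Cldn5 (-0.15), Grhl2 (0.38), H2-Eb1 (-0.44), Msr1 (-0.46), Tfrc (0.71) and Trim15 (0.34) for 24 h against 2 h of E3. The mean of probes turned Synpo2 for E3 2 h (0.29) and Ier2 for E3 24 h (0.027), and normexp turned Ccne2 for E3 24 h (0.080). Of the 92 called list tests, 0 held with an estimated correlation. The number called was 97 with fry (20 lost, 25 gained), 85 with quantile normalization, 94 with median scaling, 98 with normexp, 102 with no filter, 82 with slide as a random block, 97 with scan day as a block and 92 within scan day 1 (14 lost, 14 gained).

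Leaving out each array in turn gave 6041 to 7539 genes for E2 2 h, 7003 to 8109 for E2 24 h, 6595 to 7468 for E3 2 h, 1423 to 5306 for E3 24 h, 0 to 1 for E2 against E3 at 2 h, 1829 to 4056 at 24 h, 9142 to 10139 and 8036 to 9937 for 24 h against 2 h of E2 and E3, and 432 to 2217 for the difference of differences. The overlap ran from 5502 to 6596 at 2 h and from 1248 to 3868 at 24 h. The score difference ran from -0.110 to 0.0603 at 2 h, where its sign is not settled, and from 0.30 to 0.730 at 24 h.

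Over the 30 pairs with the same replicate number in different groups, the correlation of deviations ran from -0.22 to 0.21 (mean -0.01). With 3 per group this cannot show pairing absent, and some pairs share a slide. With the replicate block, which has fewer degrees of freedom, the counts were 7523, 8513, 7855 and 3401 for E2 2 h, E2 24 h, E3 2 h and E3 24 h against vehicle, 2742 for E2 against E3 at 24 h and 887 for the difference of differences, and 88 list tests were called.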

Other observations

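The tests of leaving out each array for gene lists, and those with scan day, were chosen only after the results were seen.

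Smooth muscle markers rose with E3 (8 of 16, 0 fell, median 0.61) and not as a list with E2 (6 of 16, 0 fell, median 0.45); the E3 call was lost with quantile normalization (median 0.22). With E2 the list was called without vehicle replicate 2 (0.46, adjusted p = 0.049), vehicle replicate 3 (0.59, 0.017) or E2 24 h replicate 3 (0.63, 0.011) and with no filter on dim probes (0.45, 0.036). The smooth muscle list had adjusted p = 4.8e-04 with E3, or adjusted p = 0.63 with an estimated correlation, and 8 passed when adjusted over the list alone. Camera gave the smooth muscle list adjusted p = 0.064 with E2, and 6 passed when adjusted over the list alone. Actg2, a smooth muscle actin, rose by 1.47 ± 0.22 (SE, n = 3 per group, adjusted p = 3.2e-04) with E2 and 1.20 ± 0.22 (adjusted p = 0.0067) with E3. The test of E2 against E3 did not separate them (median -0.11, adjusted p = 0.51). Macrophage and monocyte markers rose with E3 (5 of 16, 0 fell, median 0.87) and had a median of -0.15 with E2 (1 higher, 1 lower). The macrophage list had adjusted p = 1e-04 with E3, or adjusted p = 0.59 with an estimated correlation, and 11 passed when adjusted over the list alone. Camera gave the macrophage list adjusted p = 0.88 with E2, and the same counts passed when adjusted over the list alone. Fcgr1 rose by 1.53 ± 0.32 with E3 (adjusted p = 0.011). Lymphocyte and natural killer markers fell with E2 (8 of 18, 0 rose, median -1.39) and had a median of 0.02 with E3 (0 called). The lymphocyte list had adjusted p = 0.012 with E2, or adjusted p = 0.75 with an estimated correlation, and 9 passed when adjusted over the list alone. Camera gave the lymphocyte list adjusted p = 0.66 with E3, and 0 members passed when adjusted over the list alone. Cd2, a T cell adhesion molecule, fell by 1.81 ± 0.34 with E2. Endothelial markers fell with E2 (9 of 17, 0 rose, median -0.38), Cldn5, a tight junction gene of endothelium, by 1.07 ± 0.17, but the list was not called without vehicle replicate 2 (-0.38, 0.068) or with slide as a random block (-0.37, 0.066). The endothelial list had adjusted p = 0.031 with E2, or adjusted p = 0.67 with an estimated correlation, and 9 passed when adjusted over the list alone. Dendritic and antigen-presentation markers fell with E2 (5 of 12, 0 rose, median -0.70), but not without E2 24 h replicate 1 (-0.50, 0.069), with quantile normalization (-0.91, 0.053), with slide as a random block (-0.68, 0.088) or within scan day 1 (-0.50, 0.13). Camera gave the dendritic list adjusted p = 0.034 with E2, or adjusted p = 0.69 with an estimated correlation, and 5 passed when adjusted over the list alone.

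Erythrocyte markers, only 5 of which were tested, were higher than in vehicle with E2 at 2 h (3 rose, median 0.96) and at 24 h (4 rose, median 1.21), and had medians of 0.58 with E3 at 2 h (2 rose) and 0.88 at 24 h (3 rose). The erythrocyte list had adjusted p = 0.026 with E2 at 2 h, or adjusted p = 0.64 with an estimated correlation, and 3 passed when adjusted over the list alone. Camera gave the erythrocyte list adjusted p = 0.026 with E2 at 24 h, or adjusted p = 0.64 with an estimated correlation, and 4 passed when adjusted over the list alone. The erythrocyte list had adjusted p = 0.081 with E3 at 2 h, and 2 passed when adjusted over the list alone. It was called there without vehicle replicate 2 (0.75, 0.028) and with scan day as a block (0.91, 0.027). Camera gave the erythrocyte list adjusted p = 0.0498 with E3 at 24 h, or adjusted p = 0.70 with an estimated correlation, and 3 passed when adjusted over the list alone. Hba-a1, a haemoglobin chain, rose by 1.34 ± 0.26 (SE, n = 3 per group, adjusted p = 0.0014) with E2 at 2 h and 1.21 ± 0.26 (adjusted p = 0.0027) at 24 h. The call at 2 h was lost without E2 2 h replicate 3 (0.88, 0.057), and that at 24 h of E2 without vehicle replicate 3 (1.09, 0.052) or E2 24 h replicate 3 (0.90, 0.058). The E3 call at 24 h was lost without vehicle replicate 1 (0.80) or 3 (0.80) or E3 24 h replicate 1 (0.73) or 3 (0.76), with quantile normalization (0.62), with the replicate block (0.88) and with fry (adjusted p = 0.082). With slide as a random block none of these was called (1.01, 1.21 and 0.87). Interferon-response genes had risen as a list at 24 h of E3 (4 of 23, 0 fell, median 0.56), with medians of 0.58 with slide as a random block and 0.32 with scan day as a block. E3 24 h replicate 2 carried much of it: without that array the median was 0.22 (adjusted p = 0.048). Scan day 1 alone leaves out the same E3 array; there it was 0.22 and not called (adjusted p = 0.082). It was not called with fry (adjusted p = 0.099). The interferon list had adjusted p = 3.6e-04 with E3, or adjusted p = 0.71 with an estimated correlation, and 1 passed when adjusted over the list alone. Ribosome biogenesis genes stayed higher than vehicle at 24 h of E2 (19 of 38, 0 fell, median 0.48) and had a median of -0.04 with E3 (2 rose, 0 fell). Camera gave the ribosome biogenesis list adjusted p = 1.6e-05 with E2, or adjusted p = 0.70 with an estimated correlation, and 19 passed when adjusted over the list alone. The ribosome biogenesis list had adjusted p = 0.84 with E3, and the same counts passed when adjusted over the list alone. Without E3 24 h replicate 2 the E3 list was called lower (-0.26, 0.0013). Reference genes rose as a list at 24 h of E2 (6 of 15, 0 fell, median 0.28), though not with quantile normalization (-0.04, adjusted p = 0.23). Camera gave the reference list adjusted p = 0.0081 with E2, or adjusted p = 0.52 with an estimated correlation, and 6 passed when adjusted over the list alone.

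Genes without a symbol, a class that includes RIKEN, Gm and LOC names, fell more often at 2 h than genes with one. The shares were 29.5% of 5160 against 20.9% of 15153 with E2 and 32.9% against 20.5% with E3. Dim probes as the whole cause are argued against by the ratio of the shares among genes matched for level, at least 1.51 with either oestrogen. The scaling of the arrays as the whole cause is argued against by the same ratio with the median as the scale, at least 1.87. At 24 h, with the same vehicle arrays, shares were 38.3% against 16.9% for E2 and 23.0% against 6.47% for E3. The vehicle slide as a cause, and more unspliced or short-lived RNA, were not tested.

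The counts of changed genes were set beside other splits of the same arrays. For each comparison of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. For E2 at 2 h (7852 genes), E2 at 24 h (8814), E3 at 2 h (8169) and 24 h against 2 h of E2 and of E3, 1 of 10 splits, the real one, gave as many genes, and the highest other gave 0. For E3 at 24 h (4136 genes) and E2 against E3 at 24 h (3195) it was again 1 of 10, with 1 gene in the highest other. For E2 against E3 at 2 h, with 0 genes, all 10 splits gave as many, which is so by construction, and the highest other gave 1.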
